A study of Homo sapiens with 112 samples.

How the data were processed

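Gene expression was measured in cells of induced sputum with Affymetrix HuGene 1.0 ST arrays. Per the labels, sputum was induced with inhaled hypertonic saline, mucus plugs were picked out, the cell pellet was lysed and its RNA was purified. A small RNA input was amplified before labelling, per the labels. Each of the 112 samples has 1 array, and the labels place the samples in the groups TEA_1 (34), TEA_2 (19), TEA_3 (47) and CONTROL (12). The series text says that the TEA clusters were found by clustering expression of selected pathway genes in sputum of people with asthma. The clinical state of the CONTROL samples is not given in the sources used here, and the labels give no batch, date of hybridization or donor. Clinical features and blood samples were not analysed here.

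The deposited table holds 1 log2 expression value per probe set and array. The submitters' processing notes name RMA, whose version is not given in the sources used here. RMA corrects the probe background, applies quantile normalization over probes and summarises each probe set on the log2 scale. Which arrays were normalized together, a filter on probe sets and a batch adjustment are not given in the sources used here. The deposited values were used as they stand. The medians of the arrays lay between 5.20 and 5.38 on the log2 scale, and 125 values in 9 probe sets were below 0. The number of arrays limits the precision of each value. The p-values measure differences against the spread between samples, which can hold technical as well as biological differences. The gene fit used 1 spread per gene for all groups. On the first principal component CONTROL had an SD of 37.09, against 21.18 in TEA_1, 7.67 in TEA_2 and 13.57 in TEA_3. The p-values of contrasts with CONTROL, by gene fit or permutation, may therefore be too small.

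The table holds 22148 probe sets. Of these, 19130 have 1 gene symbol, 1734 have several and 1284 have none. Probe sets of XIST, TSIX and genes on the Y chromosome (94) were left out, while other genes on the X chromosome were kept. The gene IDs of 19099 probe sets with 1 symbol are in the reference table of gene names, and 0 symbols needed an update. Each gene was represented by its probe set with the highest mean over all arrays, which left 18255 genes. For 625 of them more than 1 probe set was available. No filter on dim probe sets was applied.

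Gene tests used limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, and eBayes with a mean-variance trend) with the 4 groups in 1 fit and no covariate. The 7 contrasts were asthma against CONTROL, each cluster against CONTROL, and each pair of clusters. For genes, asthma is the mean of the 3 cluster means with equal weights, so the largest cluster does not set it. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg within each contrast, and genes with an adjusted p under 0.05 were called. Fold differences are given with 95% intervals from the fit, on the scale of the larger group over the smaller one.

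The 40 gene lists covered cell types that sputum can hold, inflammatory and metabolic pathways, small nucleolar RNAs and olfactory receptors. Olfactory receptor genes stand for probe sets with little target RNA, so that their mean can serve as a sign of array background. The score of a list on an array was the mean of the log2 values of its genes, each centred on its mean over all arrays. Scores were compared by two-sided permutation tests with 100000 resamples, adjusted over all 280 tests of 40 lists in 7 contrasts. For the asthma contrast the scores of the 100 arrays of the clusters were pooled. Lists were also compared with the other genes by camera in limma, with a preset correlation of 0.01 and with an estimated correlation. The median difference of each list was placed among 10000 random lists matched on mean level in 20 bins. Counts of called members are given over all genes tested and adjusted over the list alone.

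Genes are named by a rule: the 10 called genes with the largest difference in each direction of each contrast, and up to 4 called members of each list by size, or 2 members where none was called. The groups, contrasts, tests, lists, naming rule and the alternatives named next were fixed before the data were examined. They were a filter on dim genes, all probe sets, averaged probe sets per gene, another variance moderation, array weights, centring or quantile normalization of arrays, a stricter adjusted p of 0.01, a least fold of 1.5, fits of the compared groups alone, 5 cell marker scores as covariates, the median of a list, brighter members of a list, genes scaled to unit variance, and separate CONTROL arrays for each contrast. The 5 marker scores were those of neutrophils, alveolar macrophages, eosinophils, squamous cells and ciliated cells. Alternatives chosen after seeing the data were the olfactory receptor score as a covariate, leaving out arrays with a median correlation under 0.9 with their own group, and leaving out single arrays of the 3 smaller groups. Alternatives of list scores used 20000 resamples.

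Principal components were computed from all 18255 genes, and the share of each of the first 5 components between groups was tested by permutation. The overlap of called genes was compared with 50 simulations in which groups shared CONTROL but no effect, and with 20 draws in which each contrast had its own CONTROL arrays, 6 each. Other splits of the same arrays into groups of the same sizes were fitted 100 times, the real split included, and for asthma against CONTROL also with the clusters pooled as 1 group. Before use, the fit was tested on simulated data in which 200 of 18255 genes were changed in each contrast. At log2 differences of 0.5 and 1, it recovered 60% and 86% of changed genes in TEA_1 against CONTROL, 56% and 87% in TEA_2 against CONTROL, 73% and 98% in TEA_3 against CONTROL and 73% and 97% in asthma against CONTROL. Between clusters it recovered 83% and 97% in TEA_1 against TEA_2, 80% and 100% in TEA_1 against TEA_3, and 80% and 96% in TEA_2 against TEA_3. False calls made up 3.8% in TEA_2 against TEA_3 to 9.1% in TEA_1 against TEA_2. The simulated noise was independent between genes and had the same spread in all groups, unlike the real arrays. These shares check the code and do not give the share of false calls in the real data. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 was used for list scores, components and plots.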

Results

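Expression was measured in sputum cells on 112 arrays, 1 per sample. The labels place 34 samples in TEA_1, 19 in TEA_2, 47 in TEA_3 and 12 in CONTROL. The series text states that the TEA clusters came from expression of pathway genes in asthma sputum, so differences between clusters on these arrays are not independent evidence of the grouping. A difference between a single cluster and CONTROL can likewise come in part from the clustering. Array medians were close, from 5.20 to 5.38 on the log2 scale. The median correlation of an array with the others of its group was 0.917 in TEA_1, 0.933 in TEA_2, 0.949 in TEA_3 and 0.941 in CONTROL. In TEA_1, 7 arrays had a median correlation under 0.9 with their own group, and in CONTROL 3 arrays did (replicates 6, 10 and 12). The number of arrays, above all the 12 of CONTROL, limits the precision of the values. The 95th percentile of the mean levels of olfactory receptor genes, 5.57, served as a level of background, chosen after the values were seen. Of 389 named genes outside that list, 133 had all group means under it, so they were not shown to be above background. No fold is given for these dim genes, but log2 differences are, and these carry the same limit. Not all of them are marked as dim where they are named. A fold against a group with a mean under that level is limited by background.

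The first principal component ordered the clusters. It held 24.76% of the variance of 18255 genes, and 64.0% of its variance lay between groups (permutation adjusted p = 5.0e-05, from a p of 1.0e-05, the smallest the resamples can give). Its mean was -33.76 ± 21.18 (SD) in TEA_1, -3.94 ± 7.67 in TEA_2 and 25.73 ± 13.57 in TEA_3. CONTROL had a mean of 1.14 ± 37.09, so its arrays spread over the range of all 3 clusters. The second component held 8.73% of the variance, with 5.14% of it between groups (adjusted p = 0.158). The fifth held 2.16%, with 13.57% between groups (adjusted p = 0.0032). When genes were scaled to unit variance, the component of the same rank had 0.66% between groups, but it can be a different axis.

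**Figure D1:**
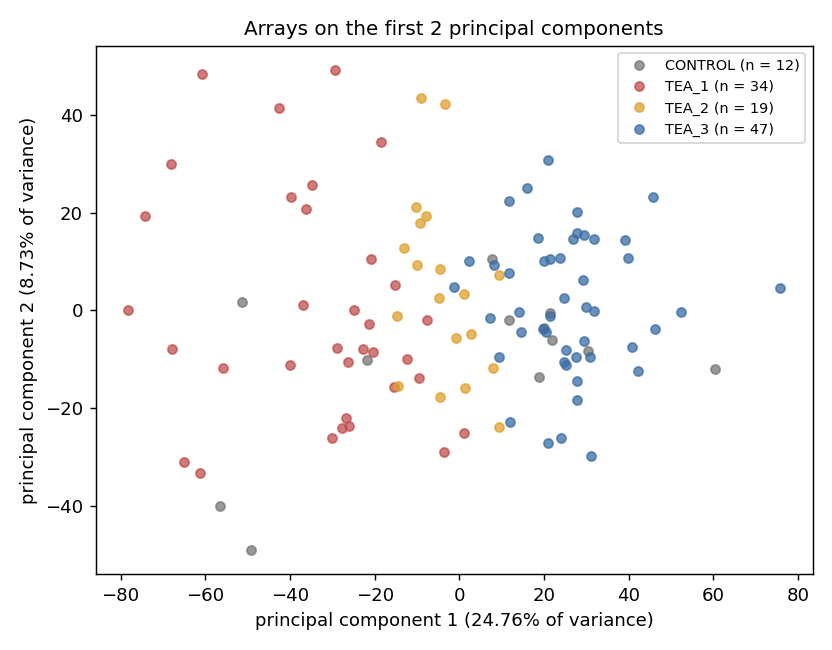
Each point is 1 of 112 arrays, placed by its scores on principal component 1 (24.76% of variance) and principal component 2 (8.73% of variance), both in log2 units, and coloured by group. TEA_1 lies at low scores of component 1, TEA_3 at high scores, TEA_2 between them, and the 12 CONTROL arrays spread along the component.

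Asthma against CONTROL asks what separates the sputum cells of the 3 clusters together (n = 100) from CONTROL (n = 12). A total of 5 genes were higher and 9 lower. MANEA, a Golgi endomannosidase that trims glycans, had a log2 difference of -1.26 ± 0.20 (SE; adjusted p = 0.000105), with 95 of 100 arrays below the CONTROL median. MT2A, a metallothionein that binds zinc, was 1.86-fold higher (95% interval 1.43 to 2.42; adjusted p = 0.0276), with 85 of 100 arrays above that median. CD300A, an inhibitory receptor of leukocytes, was 1.73-fold higher (95% interval 1.36 to 2.20) in 98 of 100 arrays.

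The other genes called higher were STX3, a syntaxin of membrane fusion (log2 difference 0.89 ± 0.21, SE), SMIM2 (0.29 ± 0.07) and STPG3 (0.26 ± 0.06). DPH6, an enzyme of diphthamide synthesis, fell by 0.92 on the log2 scale. CST6, a cystatin that inhibits cysteine proteases, fell by 0.96. PRMT3, an arginine methyltransferase, fell by 0.63, and INTS15, a subunit of the Integrator complex, fell by 0.62. OCEL1 (-0.56 ± 0.11, SE), MCEE (-0.48 ± 0.11), TRIM8 (-0.35 ± 0.07) and PPP1R36 (-0.28 ± 0.06) were the other genes called lower. MANEA and DPH6 were dim in all groups, with highest group means of 3.63 and 4.55, both in CONTROL, under the level of background. SMIM2 (highest group mean 5.0), PRMT3 (4.24), MCEE (3.68), TRIM8 (5.20) and PPP1R36 (4.12) were also dim in all groups.

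Among gene lists, scores of 3 were higher in asthma and 0 lower. Chemokine ligands, which attract leukocytes, had a score difference of 0.23 (adjusted p = 0.0147) and were above the CONTROL median in 80 of 100 arrays, with 0 of 31 members called by limma. The glucocorticoid response list differed by 0.28 (adjusted p = 0.0298), with MT2A as its called member of 15 and 5 higher and 1 lower adjusted over the list alone. Metallothioneins differed by 0.33 (adjusted p = 0.0298), with 1 of 7 called. For these 3 lists camera gave adjusted p = 0.676 with an estimated correlation. All 3 lay outside the middle 95% of random lists matched on level. Squamous epithelial markers, which come from the upper airway, had a score lower by a mean of -0.75 (adjusted p = 0.0565), with 5 of 15 members lower adjusted over the list alone. The type I interferon score differed by 0.52 (adjusted p = 0.0653) and the olfactory receptor score by 0.018 (adjusted p = 0.814).

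At an unadjusted p under 0.05, 2238 genes differed. The called genes grew to 792 higher and 264 lower without the 10 arrays that correlate poorly with their group, and to 942 and 345 with array weights, while all 3 list calls ended without those arrays, and with the olfactory receptor score removed only that of chemokine ligands held. After quantile normalization 1 list was higher and 1 lower, and of 6 alternatives the metallothionein call passed in 2 and the glucocorticoid call in 3. Leaving out 1 array at a time gave between 1 (without CONTROL 3) and 16 higher genes (without TEA_1 20), with 37 of 65 arrays moving the count over 1.5 times, and between 8 (without TEA_1 3) and 30 lower genes (without CONTROL 10), with 18 of 65 doing so.

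**Figure D2:**
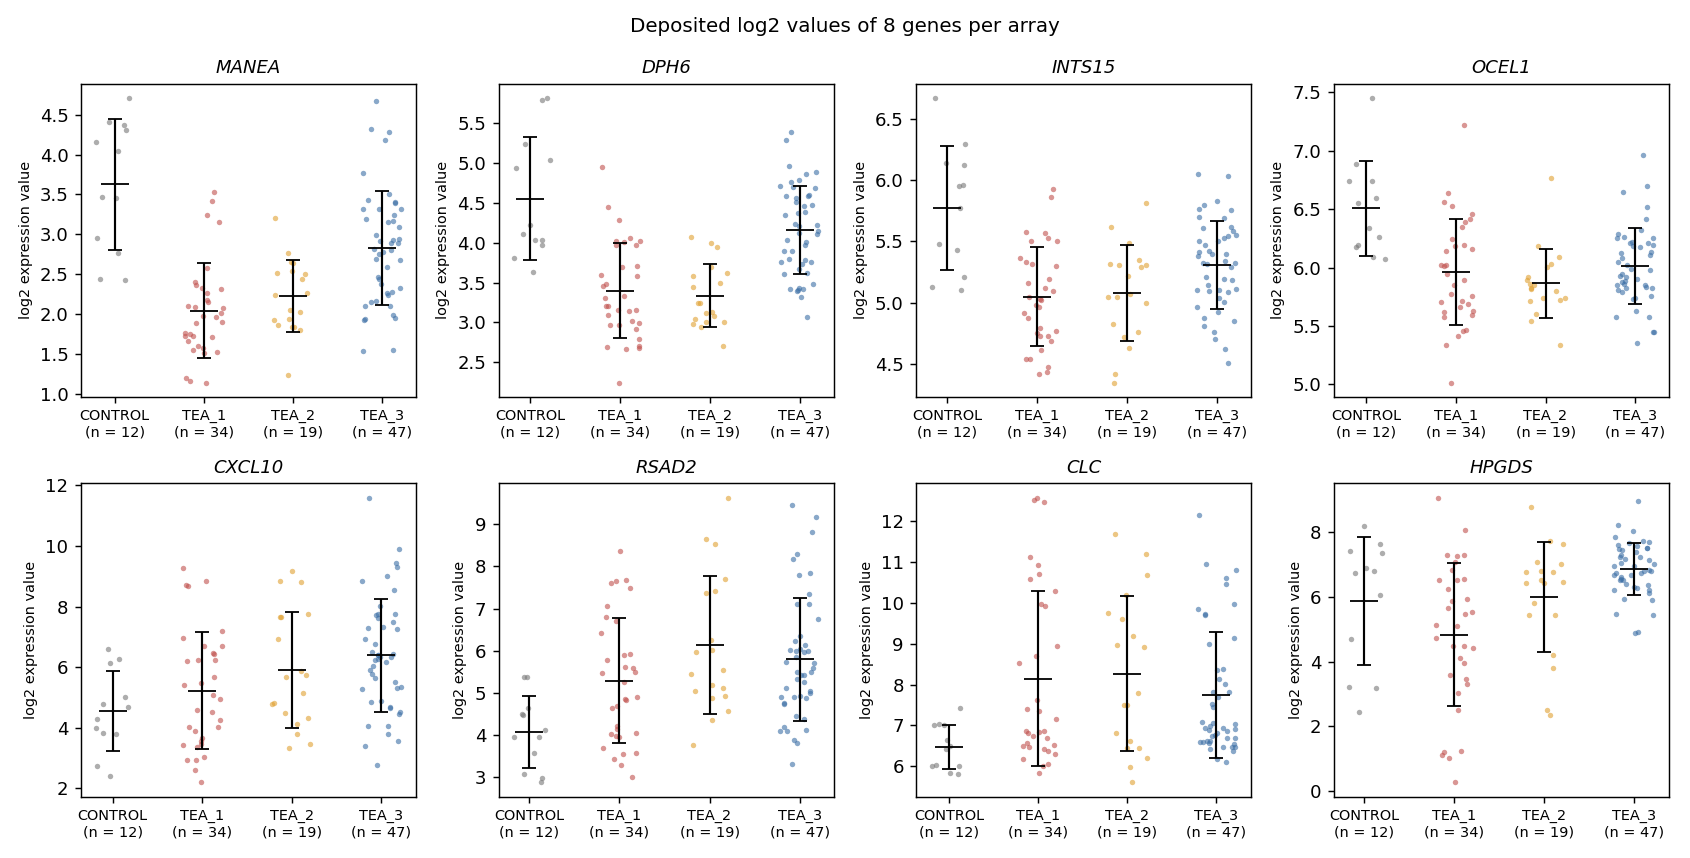
Deposited log2 values of 8 genes, 1 point per array, with bars for the mean ± SD of CONTROL (n = 12), TEA_1 (n = 34), TEA_2 (n = 19) and TEA_3 (n = 47). MANEA had a mean of 3.63 in CONTROL against 2.04 in TEA_1, 2.23 in TEA_2 and 2.83 in TEA_3, while CLC and HPGDS spread over several log2 units within clusters.

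TEA_1 (n = 34) against CONTROL (n = 12) asks how the cluster at the low end of the first component differs from CONTROL. Eosinophil genes were higher: CLC, the Charcot-Leyden crystal protein, was 3.17-fold higher (95% interval 1.45 to 6.95; adjusted p = 0.0163), above the CONTROL median in 27 of 34 arrays. CPA3, a protease of mast cells, was 2.14-fold higher (95% interval 1.28 to 3.58). The decoy receptor IL1R2 was 2.87-fold higher (95% interval 1.69 to 4.87), and the antiprotease SLPI of secretory cells 2.35-fold higher (95% interval 1.56 to 3.54) in 32 of 34 arrays. Among lower genes, the serine proteases TMPRSS11D and TMPRSS11B differed by 5.40-fold (95% interval 2.30 to 12.7) and 3.60-fold (95% interval 1.78 to 7.30). TMPRSS11B is on the list of squamous epithelial markers, whose score spread widely in CONTROL (0.67 ± 1.22, SD). Its difference may thus reflect the content of squamous cells. The fit with 5 cell marker scores as covariates cannot decide this, because TMPRSS11B is itself part of the squamous score.

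A total of 5684 genes were higher and 2123 lower, of which 12 and 169 differed at least 2-fold. The median log2 difference over all genes was 0.10, so small positive differences were common. Other large higher genes were ADGRG3 (log2 difference 1.35 ± 0.33, SE), IFITM1, an antiviral membrane protein (1.28 ± 0.41), IL18R1 (1.28 ± 0.47), P2RY14 (1.25 ± 0.48), RSAD2 (1.21 ± 0.48) and SLC25A37 (1.03 ± 0.33). Other large lower genes were LY86 (-1.72 ± 0.32), GOLPH3L (-1.68 ± 0.33), SNORA27 (-1.67 ± 0.42), RAB2B (-1.60 ± 0.28), the RNA sensor TLR7 (-1.60 ± 0.33), MANEA (-1.58 ± 0.22), MRPL35 (-1.58 ± 0.30) and TMPRSS11E (-1.56 ± 0.52). All of these but LY86 and TMPRSS11E were dim in all groups.

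Scores of 8 lists were higher and of 1 lower. Of the eosinophil markers 7 of 10 rose, and their score differed by 0.39 (adjusted p = 0.0268; 31 of 34 arrays above the CONTROL median). Besides CLC they included the prostaglandin D2 receptor PTGDR2 (0.31 ± 0.08, SE) and the granule protein PRG2 (0.26 ± 0.08), which was dim in all groups. The type 2 airway response rose in 10 of 21 members, among them IL13 (0.42 ± 0.10) and the chemokine CCL17 (0.37 ± 0.11), with a score difference of 0.24 (adjusted p = 0.00528). IL13 was dim in all groups, so a rise above background was not shown for it. Ciliated epithelial markers rose in 9 of 14 members, including FOXJ1, the regulator of cilia (0.26 ± 0.09), with a score difference of 0.21 (adjusted p = 0.00047; 34 of 34 arrays). Erythroid (6 of 8 members) and platelet markers (4 of 8) had score differences of 0.21 and 0.15 (adjusted p = 0.0268 and 0.0307). All erythroid markers measured except HBB were dim in all groups, as were the platelet markers PPBP, PF4, CLEC1B, GP1BA, TREML1 and ITGA2B. Chemokine ligands (8 of 31 members) differed by 0.23 (adjusted p = 0.029). In the glucocorticoid list, 7 of 15 members rose, including DUSP1 (0.62 ± 0.18), and MERTK fell by 0.81, with a score difference of 0.32 (adjusted p = 0.0359). Adjusted over the list alone, 7 eosinophil, 10 type 2, 9 ciliated, 7 erythroid, 4 platelet, 5 chemokine and 10 glucocorticoid members were higher. The camera calls of ciliated and erythroid markers with a preset correlation (adjusted p = 0.0275 and 0.0428) ended with an estimated one (0.681 and 0.676), and eosinophil, type 2, platelet, chemokine and glucocorticoid lists had no camera call. Of the 9 lists called by score, erythroid, platelet and chemokine lists lay within the middle 95% of random lists matched on level (percentiles 96.5, 97.2 and 96.1).

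Ribosomal proteins fell in 9 of 18 members, with RPL5 at -0.38 ± 0.11 (SE) and a score difference of -0.24 (adjusted p = 0.0405). Oxidative phosphorylation genes fell in 9 of 21 members, including ATP5F1A of ATP synthase (-0.58 ± 0.15), and lysosome genes in 6 of 24, including HEXA (-0.87 ± 0.25), although their scores did not pass (-0.34, adjusted p = 0.0799, and -0.29, adjusted p = 0.143). Their camera calls with a preset correlation gave adjusted p = 0.676 with an estimated correlation, as did ribosomal proteins. Olfactory receptors, a sign of array background, moved with these groups: 160 of 338 rose, and their score differed by 0.17 (adjusted p = 0.00229; 34 of 34 arrays). The squamous score differed by -0.68 (adjusted p = 0.166). Neutrophil markers rose in 2 of 13 members (VNN2 1.01 ± 0.42), with a score difference of 0.53 (adjusted p = 0.213).

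With the olfactory receptor score as a covariate 138 genes were higher and 42 lower. Of these 180 genes, 99 were among the 7807 called without it in the same direction, and the rest were newly called. Of the list calls only that of the glucocorticoid list held. With 5 cell marker scores as covariates 1386 genes were higher and 414 lower. Without the 10 arrays that correlate poorly with their group, the chemokine, glucocorticoid and ribosomal protein calls ended, and oxidative phosphorylation and lysosome genes were newly called lower. P2RY14 turned to -0.006 with 5 cell marker scores as covariates. Without CONTROL 3 the counts were 3694 and 1406.

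TEA_2 (n = 19) against CONTROL (n = 12) asks the same of the middle cluster. By limma 0 genes were higher and 4 were lower, with 2114 at an unadjusted p under 0.05. MANEA and DPH6, both dim, had log2 differences of -1.40 ± 0.24 (SE; adjusted p = 0.000501) and -1.22 ± 0.21 (adjusted p = 0.000501). Each was below the CONTROL median in 19 of 19 arrays. INTS15 was lower by a log2 difference of -0.69 ± 0.15 (SE; adjusted p = 0.0354) in 19 of 19 arrays and OCEL1 1.56-fold lower (95% interval 1.30 to 1.88; adjusted p = 0.0354) in 18 of 19.

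With genes above the median level only, limma called 0 genes: MANEA, DPH6 and INTS15 fell under the filter and OCEL1 missed the threshold. With centred arrays and in fits of the compared groups alone, 2 genes were lower.

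Scores of 3 lists were higher and of 0 lower. The type I interferon response, genes that restrict viruses, had a score difference of 0.69 (adjusted p = 0.0307; 16 of 19 arrays above the CONTROL median). No member was called over all genes, and 5 of 21 were higher adjusted over the list alone. Its largest members were RSAD2 (2.05 ± 0.53, SE; adjusted p = 0.0934) and the RNA sensor RIGI (1.42 ± 0.44; adjusted p = 0.155). The glucocorticoid list differed by 0.32 (adjusted p = 0.0251; 18 of 19 arrays), with 2 of 15 higher adjusted over the list alone. Eosinophil markers differed by 0.25 (adjusted p = 0.0447; 15 of 19 arrays), with CLC at 1.79 ± 0.63 (SE; adjusted p = 0.21). The camera adjusted p = 0.676 with an estimated correlation for the interferon and glucocorticoid lists and 0.687 for eosinophil markers. Eosinophil markers also lay within the middle 95% of matched random lists (percentile 86.7). The squamous score differed by -0.74 (adjusted p = 0.16), and the olfactory receptor score by 0.035 (adjusted p = 0.606).

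Without the 10 arrays that correlate poorly with their group 565 genes were higher and 277 lower, with array weights 316 and 174, and the interferon and glucocorticoid calls ended without those arrays. The interferon and eosinophil calls ended with the olfactory receptor score removed, and that of eosinophil markers also by the median over the list, where the difference was 0.047. Leaving out 1 array gave 2 to 10 lower genes: 10 without CONTROL 1, 7 without CONTROL 5 or 12, and 2 without CONTROL 6 or 7 or TEA_2 8, 12 or 19; it gave 1 higher gene without TEA_2 9 and 2 without CONTROL 9 or 12.

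TEA_3 (n = 47) against CONTROL (n = 12) asks the same of the cluster at the high end of the first component. Interferon genes were higher: CXCL10, a chemokine induced by interferon gamma, was 3.58-fold higher (95% interval 1.61 to 7.99; adjusted p = 0.0228), above the CONTROL median in 40 of 47 arrays. RSAD2, an antiviral enzyme, was 3.30-fold higher (95% interval 1.76 to 6.19; adjusted p = 0.00921) in 44 of 47 arrays, and RIGI, a dim gene, had a log2 difference of 1.35 ± 0.39 (SE) in 45 of 47. FABP3, a fatty acid binding protein, was 3.10-fold higher (95% interval 1.73 to 5.57), and FN1, fibronectin, 2.80-fold higher (95% interval 1.66 to 4.71). TMPRSS11D had a log2 difference of -1.77 ± 0.60 (SE).

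A total of 777 genes were higher and 2728 lower, of which 54 and 12 differed at least 2-fold. Other large higher genes were HLA-DQB1 (1.49 ± 0.51, SE), P2RY14 (1.46 ± 0.46), ANKRD22 (1.42 ± 0.52), CLEC6A (1.33 ± 0.41) and GBP5 (1.32 ± 0.45). Other large lower genes were TMPRSS11B (-1.57 ± 0.50), TMPRSS11E (-1.37 ± 0.50), ECM1 (-1.34 ± 0.39), S100A7 (-1.25 ± 0.41), ADGRF1 (-1.13 ± 0.39), MAL (-1.07 ± 0.38), RNASE7 (-1.04 ± 0.28), KRT78 (-1.04 ± 0.34) and HSPB8 (-1.03 ± 0.23). TMPRSS11B and MAL are on the list of squamous epithelial markers.

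Scores of 6 lists were higher and of 4 lower. The type I interferon response rose in 10 of 21 members (14 adjusted over the list alone), among them the antiviral genes IFI44L and IFIT2. Its score differed by 0.73 (adjusted p = 0.0109; 42 of 47 arrays above the CONTROL median). The interferon gamma response rose in 5 of 12 members, including GBP4 (1.21 ± 0.38, SE) and the immunoproteasome subunit PSMB9 (0.71 ± 0.22), and 1 fell. Its score differed by 0.79 (adjusted p = 0.0285). The interleukin 1 and inflammasome list rose in 3 of 20 members, AIM2 (1.07 ± 0.40), IL1R2 (1.01 ± 0.38) and CASP1 (0.60 ± 0.21), with 0 adjusted over the list alone and a score difference of 0.39 (adjusted p = 0.0325). Chemokine ligands differed by 0.24 (adjusted p = 0.0165), with CXCL10, CCL18 and CCL23 up and CXCL12 down among 31. Metallothioneins differed by 0.35 (adjusted p = 0.0161), with MT2A at 1.05 ± 0.20. Heat shock genes differed by 0.20 (adjusted p = 0.0489), with 2 of 11 up. For the 6 higher lists camera gave adjusted p = 0.676 with an estimated correlation.

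Neutrophil granule genes, made in bone marrow precursors, fell in 5 of 13 members, among them ELANE (-0.25 ± 0.07, SE), with a score difference of -0.16 (adjusted p = 0.0242). Markers of B and plasma cells fell in 2 of 12 (PAX5 and BLK), with a score difference of -0.20 (adjusted p = 0.0203). Erythroid markers differed by -0.14 (adjusted p = 0.0325) with 0 of 8 called by limma. Olfactory receptors fell in 48 of 338 (32 adjusted over the list alone), with a score difference of -0.10 (adjusted p = 0.0203; 35 of 47 arrays below the CONTROL median), and moved with these groups. Squamous markers fell in 4 of 15 (7 adjusted over the list alone), with a score difference of -0.81 (adjusted p = 0.0612). The class II genes HLA-DQB1 and HLA-DQA1 (1.25 ± 0.31) were higher, while the class II score did not pass (0.28, adjusted p = 0.0606). The neutrophil score differed by 0.27 (adjusted p = 0.475) and the macrophage score by 0.38 (adjusted p = 0.0557). Of the 10 called lists 5 lay within the middle 95% of matched random lists: B and plasma cell (percentile 4.2), erythroid (10.6), chemokine (75.3), metallothionein (87.1) and heat shock lists (77.5).

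The gene counts rested on a few CONTROL arrays: without the 10 arrays that correlate poorly with their group 0 genes were higher by limma and 9 lower (1525 at an unadjusted p under 0.05), with the same counts for the olfactory receptor score as a covariate (1787), and both ended the type I interferon call (score differences of 0.63 and 0.595). All list calls of this contrast that could be tested ended with that score removed, which left 0 higher and 0 lower. Without the 10 arrays only the metallothionein call held, and squamous markers were newly called lower. Of 6 alternatives the heat shock call passed in 2 and the erythroid, interleukin 1 and chemokine calls in 3 each, and of 5 the olfactory receptor call in 3. The higher and lower counts were 394 and 1372 without CONTROL 1, 1351 and 4492 without CONTROL 3, 129 and 533 without CONTROL 6, 136 and 508 without CONTROL 10, and 285 and 1085 without CONTROL 12. MANEA, RGS14, TRIM8, FAM83A and PPP1R36 were lower both without the 10 arrays and with the olfactory receptor score as a covariate, named after their values were seen. These alternatives are not independent checks. CONTROL 6, 10 and 12, which were left out, had the highest olfactory receptor scores of CONTROL (0.263, 0.221 and 0.220, next 0.133 in CONTROL 1). MANEA, TRIM8 and PPP1R36 were dim in all groups, and RGS14 and FAM83A were not compared with the level of background.

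The 3 contrasts with CONTROL share its 12 arrays, so their calls are not independent. INTS15, MANEA and OCEL1 were lower in all 3 clusters. In TEA_1 and TEA_3, 52 genes were higher in both, 75 lower in both and 1141 called in opposite directions. Simulations with a shared CONTROL and no effect gave means of 41 genes higher in both and 123 lower in both. Across genes, which are not independent replicates, the differences of TEA_1 and TEA_3 correlated at -0.219, against 0.746 in these simulations. With separate CONTROL arrays for each contrast the correlation was -0.266 and the mean count in opposite directions 903. TEA_1 and TEA_2 shared 4 lower genes (simulated mean 49.8) and TEA_2 and TEA_3 shared 3 (152), with correlations of 0.627 and 0.470 against simulated ones of 0.680 and 0.742. With separate CONTROL arrays the correlations were 0.385 and 0.0562. The covariances were 0.0427 for TEA_1 and TEA_2 (simulated 0.0189, with separate CONTROL arrays 0.0303), 0.0255 for TEA_2 and TEA_3 (0.018 and -0.00147) and -0.0174 for TEA_1 and TEA_3 (0.0167 and -0.0315).

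TEA_1 (n = 34) against TEA_3 (n = 47) compares both ends of the first component. Macrophage, mitochondrial and lysosomal genes were lower in TEA_1. HPGDS, a prostaglandin D2 synthase, was 4.08-fold lower (95% interval 2.49 to 6.67; adjusted p = 3.82e-07), below the TEA_3 median in 27 of 34 arrays. MTREX, a helicase of nuclear RNA decay, was 3.77-fold lower (95% interval 2.99 to 4.74) in 33 of 34 arrays. Secretory epithelial genes were higher: BPIFB1, a secreted airway protein, by 1.86-fold (95% interval 1.30 to 2.67) and SLPI by 1.68-fold (95% interval 1.28 to 2.21).

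A total of 9998 genes were higher and 4922 lower, 81.7% of the genes tested, with 0 at least 2-fold higher, 710 at least 2-fold lower and 15050 at an unadjusted p under 0.05 by limma. The median size of the called differences was 0.35 on the log2 scale, and the median difference over all genes 0.18. Other large lower genes were MACC1 (-1.93 ± 0.25, SE), NSUN3 (-1.91 ± 0.21), PGGT1B (-1.90 ± 0.23), HDHD2 (-1.85 ± 0.20), CPE (-1.84 ± 0.28), CLEC6A (-1.84 ± 0.28), ARL15 (-1.83 ± 0.25) and ABRAXAS2 (-1.80 ± 0.20). All of these but PGGT1B were dim in all groups, so a loss of expression was not shown for them. Other large higher genes were ADGRG3 (0.80 ± 0.22), REXO1L1P (0.78 ± 0.10), CPA3 (0.72 ± 0.25), KRT19 (0.69 ± 0.24), WFDC2 (0.69 ± 0.12), CD24 (0.69 ± 0.21), G0S2 (0.67 ± 0.12) and ADAD2-AS1 (0.66 ± 0.08).

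Scores of 13 lists were higher and of 10 lower in TEA_1. Alveolar macrophage markers fell in 13 of 14 members, including PPARG, a regulator of macrophage identity (-1.36 ± 0.21, SE), and MSR1 (-0.99 ± 0.19). Their score differed by -0.73 (adjusted p = 0.0002; 29 of 34 arrays below the TEA_3 median). Oxidative phosphorylation genes fell in 19 of 21 members, including NDUFB5 of complex I (-1.03 ± 0.17) and UQCRH of complex III (-1.01 ± 0.17), with a score difference of -0.54 (adjusted p = 0.0002). Lysosome genes fell in 19 of 24, including the dim gene GLB1 (-1.10 ± 0.17), with a score difference of -0.44 (adjusted p = 0.0002). Ribosomal proteins fell in 13 of 18, with RPL13 higher, and a score difference of -0.18 (adjusted p = 0.00539). Cholesterol synthesis fell in 7 of 13, including the dim gene SC5D (-0.87 ± 0.11), with 3 higher and a score difference of -0.23 (adjusted p = 0.00035). Cell cycle genes differed by -0.12 (adjusted p = 0.0371), with 9 lower and 7 higher of 21 and the sign turned to 0.30 (adjusted p = 0.001) among brighter members.

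Interferon, class II and eicosanoid lists were lower as well. The type I interferon response fell in 13 of 21 members, including the dim gene IFI44L (-1.54 ± 0.28, SE) and OAS2 (-1.22 ± 0.17), with 2 higher and a score difference of -0.60 (adjusted p = 0.00074; 28 of 34 arrays). The interferon gamma response fell in 6 of 12, including the dim gene CXCL11 (-1.17 ± 0.34), and rose in 1, with a score difference of -0.50 (adjusted p = 0.0405). Class II presentation fell in 4 of 9 and rose in 1, including HLA-DMB (-0.93 ± 0.18), with a score difference of -0.35 (adjusted p = 0.0021). Eicosanoid genes differed by -0.20 (adjusted p = 0.00047), with 6 lower, among them the leukotriene enzyme LTA4H (-0.98 ± 0.18), and 5 higher of 16. Camera with an estimated correlation called 0 lists in any contrast, and its lowest adjusted p was 0.676.

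Secretory epithelial markers rose in 9 of 13 members, with TFF3, a trefoil factor of mucus, at 0.51 ± 0.07 (SE) and a score difference of 0.47 (adjusted p = 0.00035; 30 of 34 arrays). General epithelial markers rose in 8 of 11 and ciliated markers in 12 of 14, with score differences of 0.32 (adjusted p = 0.00528) and 0.27 (adjusted p = 0.0002). Eosinophil markers rose in 7 of 10, including PTGDR2 (0.47 ± 0.05) and EPX (0.39 ± 0.05), with a score difference of 0.33 (adjusted p = 0.00213). The type 2 response rose in 16 of 21, including the dim gene IL13 (0.43 ± 0.07), and fell in 2, with a score difference of 0.22 (adjusted p = 0.0002). Erythroid (8 of 8 members, 0.34), platelet (5 of 8, 0.23), neutrophil granule (9 of 13, 0.25), B and plasma cell (9 of 12, 0.23), dendritic (7 of 11, 0.26), interleukin 17 (8 of 20, 0.20) and immediate early lists (7 of 15, 0.20) were also higher by score, with adjusted p between 0.0002 and 0.029. Neutrophil markers rose in 5 of 13 without a score call (0.26, adjusted p = 0.31).

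Of the 23 lists called by score, 11 had a median difference within the middle 95% of random lists matched on level, so they did not differ from the genes around them by this test. Among higher lists these were platelet (percentile 69.2), dendritic (79.3), B and plasma cell (82.0), general epithelial (84.9), ciliated (93.1), immediate early (95.03) and interleukin 17 lists (96.0). Matched lists had medians of 0.194 for platelet, 0.183 for dendritic and 0.190 for B and plasma cell markers. Among lower lists they were lysosome (3.06), class II (18), eicosanoid (25) and ribosomal protein lists (30.5), the last with a median of -0.201 against -0.150 for matched lists.

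Olfactory receptors moved with all of these groups: 333 of 338 were higher (336 adjusted over the list alone), with a score difference of 0.27 (adjusted p = 0.0002, 34 of 34 arrays above the TEA_3 median). Their score had a mean of 0.16 ± 0.10 (SD) in TEA_1, 0.019 ± 0.05 in TEA_2, -0.12 ± 0.06 in TEA_3 and -0.016 ± 0.18 in CONTROL. With that score as a covariate, limma called 1 gene higher (BCLAF1, 0.84 ± 0.18, SE, from -0.56 without the covariate) and 2 lower (RAB2B, -1.51 ± 0.30, and VPS72, -0.84 ± 0.17), named after their values were seen. HPGDS turned from -2.03 to 0.082 (adjusted p = 0.982). List calls that held when the score was removed were those of secretory epithelial, erythroid and class II genes, and the glucocorticoid and the glycolysis and hypoxia lists were newly called. Of the erythroid markers only HBB was above the level of background in any group. The other list calls ended, among them macrophage and oxidative phosphorylation genes, and lysosome genes turned from -0.44 to 0.009. CD24 turned to -0.072 with 5 cell marker scores as covariates. Without the 10 arrays that correlate poorly with their group, the interleukin 17 and cell cycle calls ended. Of 6 alternatives the cell cycle call passed in 2, once with the sign turned, and the interferon gamma call in 3.

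**Figure D3:**
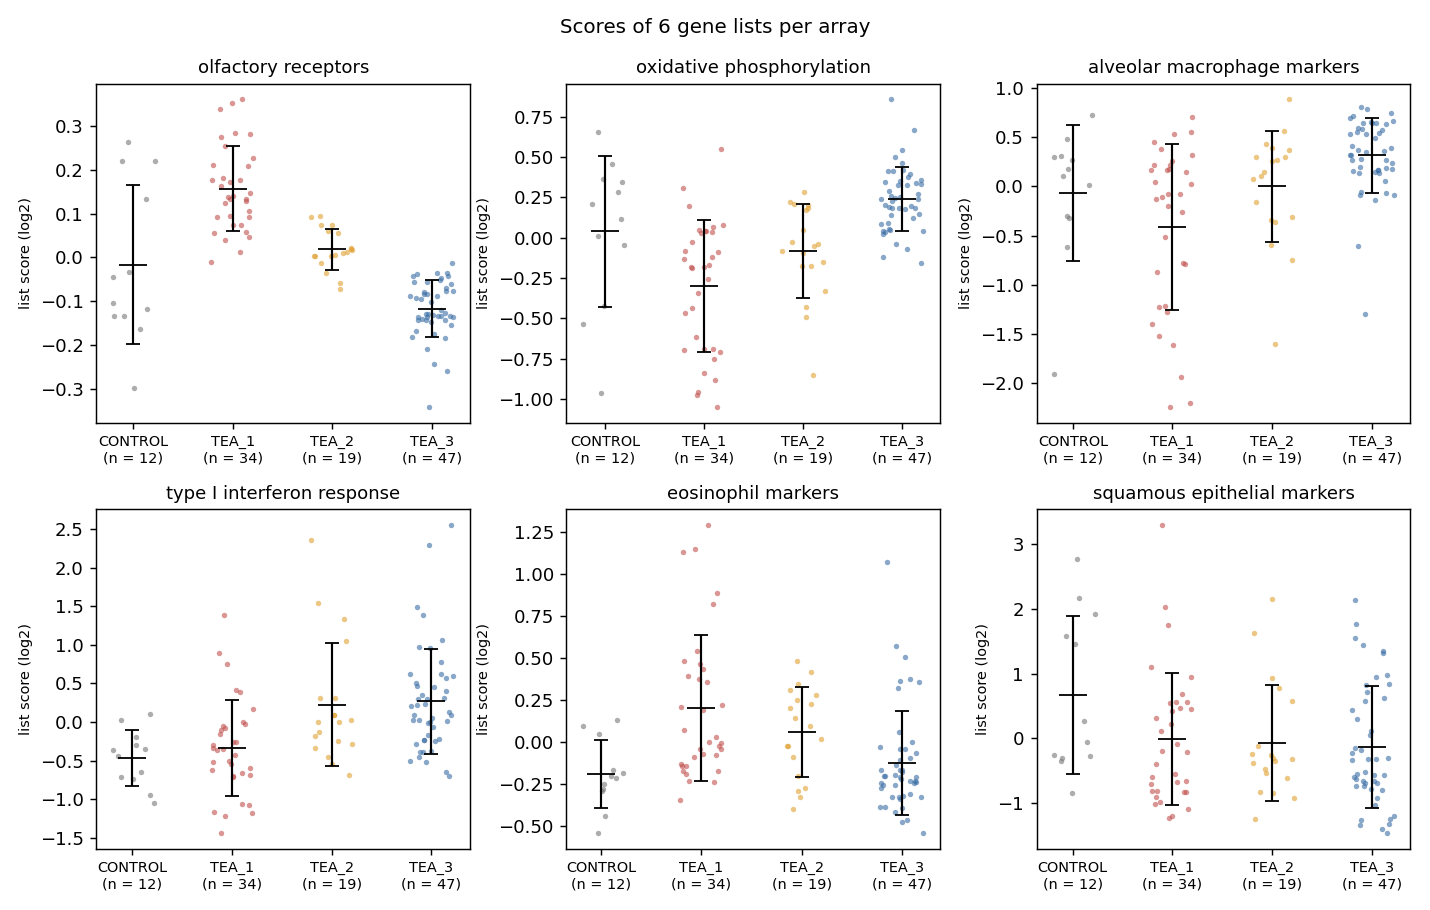
Scores of 6 gene lists in log2 units, 1 point per array, with bars for the mean ± SD of CONTROL (n = 12), TEA_1 (n = 34), TEA_2 (n = 19) and TEA_3 (n = 47). Olfactory receptor scores had means of 0.16 in TEA_1, 0.019 in TEA_2 and -0.12 in TEA_3, and oxidative phosphorylation scores went the other way, with means of -0.30, -0.083 and 0.24.

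TEA_1 (n = 34) against TEA_2 (n = 19) compares the low end with the middle. Interferon genes were lower in TEA_1: IFI44L, a dim gene, had a log2 difference of -1.20 ± 0.36 (SE; adjusted p = 0.00608), lower in 28 of 34 arrays. The histone gene H4C3 was 3.35-fold lower (95% interval 1.94 to 5.76) and MINPP1, a dim inositol phosphatase gene, had a log2 difference of -1.48 ± 0.34 (SE). DOK3, an adaptor of immune receptors, was 1.34-fold higher (95% interval 1.21 to 1.49) in 34 of 34 arrays. A total of 6410 genes were higher, 0 of them at least 2-fold, and 1387 lower, 47 of them at least 2-fold, with 9366 at an unadjusted p under 0.05 by limma.

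The type I interferon response fell in 11 of 21 members, including IFIT1 (-1.06 ± 0.41, SE), and rose in 1, with a score difference of -0.56 (adjusted p = 0.0305) and camera adjusted p = 0.676 with an estimated correlation. Alveolar macrophage markers fell in 4 of 14, including MSR1 (-0.80 ± 0.24), without a score call (-0.41, adjusted p = 0.166). Ciliated markers rose in 8 of 14 (score difference 0.14, adjusted p = 0.0065), B and plasma cell markers in 6 of 12 (0.18, adjusted p = 0.00317), erythroid in 6 of 8 (0.17, adjusted p = 0.0144), neutrophil granule genes in 5 of 13 (0.11, adjusted p = 0.0322) and platelet markers in 4 of 8 (0.10, adjusted p = 0.0305). Olfactory receptors moved with them: 153 of 338 were higher, with a score difference of 0.14 (adjusted p = 0.0002; 32 of 34 arrays above the TEA_2 median). Lysosome genes were lower in 8 of 24 and oxidative phosphorylation genes in 4 of 21, without score calls (adjusted p = 0.0733 and 0.145). Of the 7 called lists 4 lay within the middle 95% of matched random lists: platelet (percentile 69.0), erythroid (78.5), neutrophil granule (87.6) and B and plasma cell lists (96.1).

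Other large lower genes were SNORD56B (-1.37 ± 0.49, SE), SNORA33 (-1.34 ± 0.41), COMMD2 (-1.34 ± 0.33), MACC1 (-1.34 ± 0.32), WASHC3 (-1.28 ± 0.25), ARL15 (-1.28 ± 0.32) and EFR3A (-1.27 ± 0.22). Of these SNORA33, MACC1, WASHC3 and ARL15 were dim in all groups. Other large higher genes, from SNORD61 (0.57 ± 0.24) and OR2B11 (0.55 ± 0.17) to BHLHA9 and ADIRF (each 0.42 ± 0.09), included APOBR, CSRP2, ADAD2-AS1, ATP2A3 and UCN2. With the olfactory receptor score as a covariate limma called 0 genes in either direction (1043 at an unadjusted p under 0.05), and 0 list calls held when that score was removed, the interferon list included. Without the 10 arrays that correlate poorly with their group, 3928 genes were higher and 573 lower, and the neutrophil granule, erythroid and platelet calls ended. Of 6 alternatives the neutrophil granule call passed in 1, the platelet call in 2 and the erythroid call in 3.

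TEA_2 (n = 19) against TEA_3 (n = 47) compares the middle with the high end. Secretory products of the airway were higher in TEA_2: STATH, a salivary and glandular protein, by 1.95-fold (95% interval 1.25 to 3.03; adjusted p = 0.0154), SLPI by 1.66-fold (95% interval 1.19 to 2.31) and BPIFA1, a secreted airway protein, by 1.44-fold (95% interval 1.07 to 1.93). GTF2H5, a subunit of a transcription factor that also serves DNA repair, had a log2 difference of -1.31 ± 0.24 (SE), lower in 18 of 19 arrays, and TLR7 one of -1.02 ± 0.27, both dim. A total of 5095 genes were higher, 0 of them at least 2-fold, and 2169 lower, 9 of them at least 2-fold, with 9219 at an unadjusted p under 0.05 by limma.

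Secretory epithelial markers rose in 7 of 13 members, including WFDC2 (0.46 ± 0.15, SE), with a score difference of 0.39 (adjusted p = 0.0198; 17 of 19 arrays). Ciliated markers rose in 4 of 14 (0.13, adjusted p = 0.0285), neutrophil granule genes in 7 of 13 (0.14, adjusted p = 0.0128), erythroid markers in 5 of 8 (0.18, adjusted p = 0.0002), platelet markers in 2 of 8 (0.12, adjusted p = 0.00338) and the type 2 response in 7 of 21 (0.12, adjusted p = 0.0405). Oxidative phosphorylation genes fell in 7 of 21, including NDUFB5 (-0.84 ± 0.21), with a score difference of -0.32 (adjusted p = 0.0002). Lysosome genes fell in 4 of 24 (-0.20, adjusted p = 0.00792) and macrophage markers in 1 of 14, GPD1 (-0.54 ± 0.19), with a score difference of -0.32 (adjusted p = 0.0401). Class II genes differed by -0.26 (adjusted p = 0.0298) with 0 of 9 called by limma. Olfactory receptors moved with these groups: 158 of 338 were higher, with a score difference of 0.14 (adjusted p = 0.0002; 19 of 19 arrays). The type I interferon scores of TEA_2 and TEA_3 differed by -0.044 (adjusted p = 0.872). Of the 11 called lists 5 lay within the middle 95% of matched random lists: class II (percentile 4.67), lysosome (7.85), platelet (88.5), erythroid (93.1) and ciliated lists (95.5).

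Other large higher genes ran from MTND2P28 (0.72 ± 0.28, SE) and REXO1L1P (0.56 ± 0.12) to SFN (0.48 ± 0.09) and CYP4F3 (0.48 ± 0.20), with EGR3, CYTH4 and OSM between them. Other large lower genes were LYAR (-1.18 ± 0.23), TOMM22 (-1.15 ± 0.38), SUGT1 (-1.13 ± 0.25), INTS13 (-1.10 ± 0.18), CPE (-1.05 ± 0.33), RAD50 (-1.01 ± 0.23), METTL14 (-1.01 ± 0.17) and EXOC2 (-0.98 ± 0.17). All of these but TOMM22 were dim in all groups. With the olfactory receptor score as a covariate limma called 0 genes in either direction (1611 at an unadjusted p under 0.05), and 0 list calls held when that score was removed. The macrophage and type 2 calls ended without the 10 arrays that correlate poorly with their group, and of 6 alternatives they passed in 1 and 3.

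**Figure D4:**
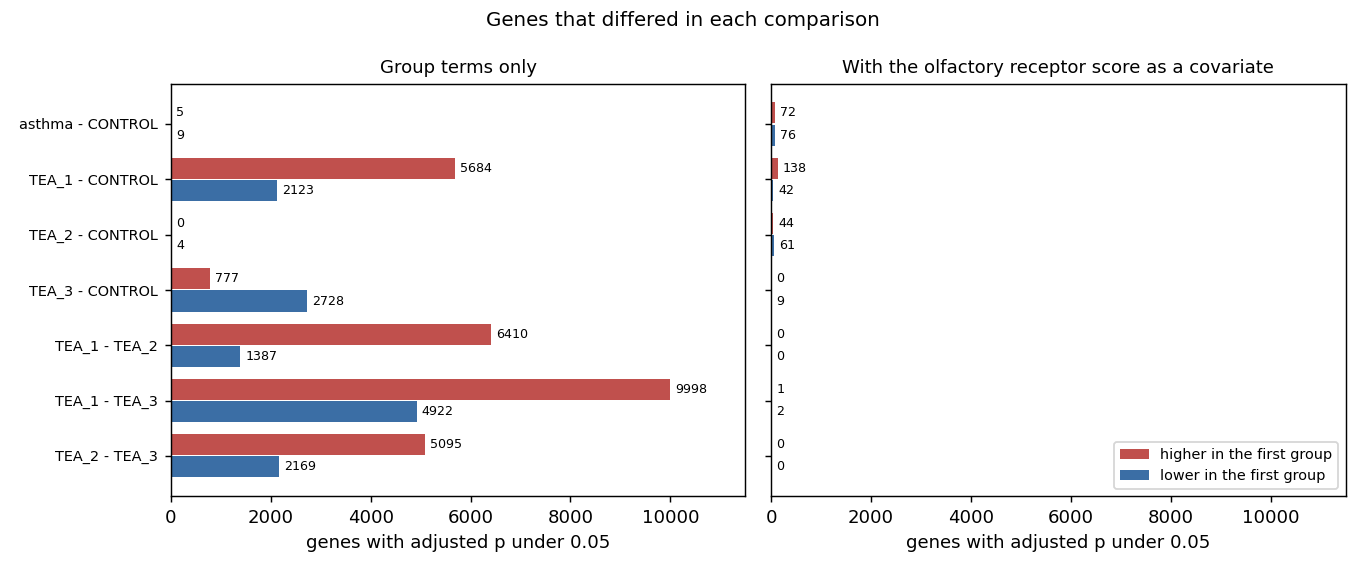
Bars give the number of genes with an adjusted p under 0.05 that were higher or lower in the first group of each comparison, with group terms only (left) and with the olfactory receptor score of the array as a covariate (right). TEA_1 against TEA_3 went from 9998 higher and 4922 lower genes to 1 and 2, and TEA_2 against CONTROL from 0 and 4 to 44 and 61.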

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

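All tests of this part were chosen only after the results were seen, except that of cell composition for the interferon list; that of oxidative phosphorylation transcripts was planned before but its interval was changed after. The change covered the interval around each percentage. Bootstrap intervals from 50 resamples lay below their own estimates for array background, so a jackknife over 20 blocks of arrays replaced them. By the bootstrap, array background would have been decided for TEA_1 against TEA_3 (66.6 to 88.3%) but left undecided for TEA_1 against TEA_2 (42.9 to 80.1%) and TEA_2 against TEA_3 (39.4 to 74.3%).

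Probe sets with no gene name or with several, 2947 in all, took no part in the comparisons of genes and drew attention because some were above their level in CONTROL. Of these, 956 were higher in TEA_1 than in CONTROL and 229 lower, 2 were higher in TEA_2 and 3 lower, and 82 were higher in TEA_3 and 379 lower. TEA_1 and TEA_3 leaned in opposite directions here as among named genes.

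The first pattern is the broad difference between clusters, 14920 of 18255 genes in TEA_1 against TEA_3. The olfactory receptor score accounted for 93.3% of the squared log2 differences of the other genes (jackknife interval 81.1 to 105.4), and for 101.8% (92.9 to 110.7) in TEA_1 against TEA_2 and 84.7% (60 to 109.4) in TEA_2 against TEA_3, which is consistent with 1 shared axis of array signal, though TEA_1 against TEA_2 and TEA_2 against TEA_3 were decided only by the jackknife. Oxidative phosphorylation transcripts accounted for 49.6% (28.6 to 70.7) and the 5 cell marker scores for 62.2% (41.9 to 82.5), and without CONTROL and the 10 arrays that correlate poorly with their group for 25.7% and 38.5% (array background 97.8%), so whether cell mix accounts for most of the difference cannot be told apart with these intervals and shifts, and the olfactory receptor difference itself was still 0.18 (95% interval 0.135 to 0.226) with the marker scores, from 0.27. The covariate shows that the differences share an axis, not what made it: RNA input, labelling or RNA quality may have set it, and so may a biological state that changes many transcripts at once, and no label separates them. The clusters were also defined from expression in these samples, so such an axis could have entered their definition.

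The second pattern is the higher type I interferon list in TEA_3 than in CONTROL, a score difference of 0.734 (SE 0.213; 95% interval 0.312 to 1.16; adjusted p = 0.0109). It was 0.595 (SE 0.221; 0.157 to 1.03) with array background removed, 0.63 (SE 0.241; 0.151 to 1.11) without the 3 CONTROL arrays that correlate poorly with their group, and 0.676 (SE 0.211; 0.258 to 1.09) with the 5 cell marker scores, so none of these alone accounts for all of it. The list call nevertheless ended in the first and second of these, where the difference was smaller and its SE larger. That call came from a separate permutation test adjusted over all lists and contrasts, so the reason it ended was not tested. Over 6 alternatives its adjusted p ran from 0.00358 to 0.0589. TEA_3 was itself defined from expression in these samples, so the clustering could have set part of the difference, which was not tested. An infection or another interferon stimulus in TEA_3 is a candidate explanation that was not tested either. A difference between the TEA_2 and TEA_3 scores (-0.044, adjusted p = 0.872) was not detected.

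The third pattern is the lower MANEA, DPH6, INTS15 and OCEL1 in TEA_2 than in CONTROL, with a mean log2 difference of -0.988; MANEA and DPH6 were under the level of background in all groups, and with genes above the median level only 3 of the 4 were not tested and OCEL1 missed the threshold. The mean was -0.955 with array background as a covariate, -1.104 without the 10 arrays and -0.931 with the 5 cell marker scores. In each, the 95% interval of every gene lay beyond 25% of its unadjusted difference, by a rule set after a first one on thresholds. That argues against each of these as the whole cause. The olfactory receptor score differed little between TEA_2 and CONTROL (0.035, permutation adjusted p = 0.606), so as a covariate it could move these genes little. The genes were picked as those called in this contrast, so their differences can be overstated, which weakens the argument. With the marker scores the call of OCEL1 ended (-0.607, SE 0.151, 95% interval -0.907 to -0.308, from -0.643, SE 0.137; adjusted p = 0.11), mainly because its error grew, so a part played by cell composition stays open there. A batch of CONTROL arrays could lower or raise single probe sets in this way, but no label gives a batch and it was not tested. A difference between asthma and CONTROL in these genes also stays open, as no biological explanation was tested.

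Chance was examined by fitting 100 splits of the same arrays into groups of the same sizes, the real one included. With the clusters pooled as 1 group, asthma against CONTROL gave 7 genes, 5 of 100 splits gave as many and the highest other gave 388, so chance cannot be excluded for that contrast. The cause of the larger count was not tested. For the other fits the real split used clusters made from expression in these samples, which random splits lack, so the splits decide nothing about chance. In those fits 1 of 100 splits, the real one, gave the most genes in asthma against CONTROL (14, highest other 8), TEA_1 against CONTROL (7807, 3625), TEA_3 against CONTROL (3505, 20), TEA_1 against TEA_2 (7797, 816), TEA_1 against TEA_3 (14920, 8) and TEA_2 against TEA_3 (7264, 18). In TEA_2 against CONTROL 3 of 100 gave at least 4 genes and another split called 2654. The cause of that count was not tested either.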

How the results depend on the processing

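The olfactory receptor score as a covariate or removed from list scores, leaving out the 10 arrays that correlate poorly with their group and leaving out single arrays were chosen only after the results were seen, while the other alternatives were fixed before. Counts within 1.5 times of the reported count are not listed. The deposited values hold no separate measure of signal over background, so the olfactory receptor score stands in for it.

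With genes above the median level only, where fewer genes were tested, limma called 3 higher and 2 lower in asthma against CONTROL, 3043 higher and 826 lower in TEA_1 against CONTROL, 0 lower in TEA_2 against CONTROL and 1815 lower in TEA_3 against CONTROL. It called 3351 higher and 815 lower in TEA_1 against TEA_2, 4598 higher and 2580 lower in TEA_1 against TEA_3 and 2830 higher and 799 lower in TEA_2 against TEA_3 under that setting. With array weights, limma called 942 higher and 345 lower in asthma against CONTROL, 316 higher and 174 lower in TEA_2 against CONTROL and 26 higher and 62 lower in TEA_3 against CONTROL. After quantile normalization, limma called 3 higher in asthma against CONTROL. At an adjusted p under 0.01, a stricter threshold, limma called 0 higher in asthma against CONTROL, 3231 higher and 1065 lower in TEA_1 against CONTROL, 2 lower in TEA_2 against CONTROL and 121 higher and 579 lower in TEA_3 against CONTROL. It called 3927 higher and 516 lower in TEA_1 against TEA_2 and 2662 higher and 975 lower in TEA_2 against TEA_3 under that setting. With a least fold of 1.5, which can only lower a count, limma called 3 higher and 5 lower in asthma against CONTROL, 81 higher and 1066 lower in TEA_1 against CONTROL, 435 higher and 26 lower in TEA_3 against CONTROL and 0 higher and 552 lower in TEA_1 against TEA_2. It called 21 higher and 2368 lower in TEA_1 against TEA_3 and 3 higher and 535 lower in TEA_2 against TEA_3 under that setting. In fits of the compared groups alone, limma called 1 higher in asthma against CONTROL, 2 lower in TEA_2 against CONTROL and 1318 higher in TEA_3 against CONTROL. With all probe sets, where more features were counted, limma called 2 higher and 9 lower in TEA_2 against CONTROL. With arrays centred on their median, limma called 2 lower in TEA_2 against CONTROL. With 5 cell marker scores as covariates, limma called 17 lower in asthma against CONTROL, 1386 higher and 414 lower in TEA_1 against CONTROL, 67 higher and 127 lower in TEA_3 against CONTROL and 1271 higher and 163 lower in TEA_1 against TEA_2. That setting gave 2556 lower in TEA_1 against TEA_3 and 1601 higher and 511 lower in TEA_2 against TEA_3. With the olfactory receptor score as a covariate, limma called 72 higher and 76 lower in asthma against CONTROL, 138 higher and 42 lower in TEA_1 against CONTROL, 44 higher and 61 lower in TEA_2 against CONTROL and 0 higher and 9 lower in TEA_3 against CONTROL. That setting gave by limma 0 higher and 0 lower in TEA_1 against TEA_2 (1043 at an unadjusted p under 0.05), 1 higher and 2 lower in TEA_1 against TEA_3 and 0 higher and 0 lower in TEA_2 against TEA_3 (1611 at an unadjusted p under 0.05). Without the 10 arrays that correlate poorly with their group, where fewer samples were fitted, limma called 792 higher and 264 lower in asthma against CONTROL, 565 higher and 277 lower in TEA_2 against CONTROL, 0 higher and 9 lower in TEA_3 against CONTROL and 3928 higher and 573 lower in TEA_1 against TEA_2. Unless a sentence names it, the cause was not tested.

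By the median over a list, score calls numbered 1 lower in asthma against CONTROL, 13 higher in TEA_1 against CONTROL, 10 higher in TEA_1 against TEA_2 and 11 higher in TEA_2 against TEA_3. With brighter members alone, score calls numbered 6 higher and 1 lower in asthma against CONTROL and 10 higher in TEA_3 against CONTROL. For list scores after quantile normalization, score calls numbered 1 higher and 1 lower in asthma against CONTROL. For list scores with centred arrays, score calls numbered 2 lower in TEA_1 against TEA_2. With the olfactory receptor score removed, score calls numbered 1 higher in asthma against CONTROL, 1 higher and 0 lower in TEA_1 against CONTROL, 1 higher in TEA_2 against CONTROL and 0 higher and 0 lower in TEA_3 against CONTROL. They numbered 0 higher and 0 lower in TEA_1 against TEA_2, 4 higher and 1 lower in TEA_1 against TEA_3 and 0 higher and 0 lower in TEA_2 against TEA_3. Among list scores without the 10 arrays, score calls numbered 0 higher and 1 lower in asthma against CONTROL, 2 lower in TEA_1 against CONTROL, 1 higher and 1 lower in TEA_3 against CONTROL and 3 higher in TEA_1 against TEA_2. The cause was not tested.

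Among named genes, 51 of 7870 values turned direction, 1380 kept it but lost the threshold, 66 gained it and 6373 kept both, and each of those 51 had an adjusted p over 0.05. Outside the genes named by rule, BCLAF1 turned from -0.557 to 0.84 (adjusted p = 0.0474) in TEA_1 against TEA_3 with the olfactory receptor score as a covariate. The following log2 differences turned with the olfactory receptor score as a covariate. In TEA_1 against CONTROL they were TGM1 (-0.007), MUC5B (-0.030), ALAS2 (-0.004), IRF7 (-0.049) and SOCS1 (-0.092). In TEA_1 against TEA_2 they were CSF3 (-0.005), IL17A (-0.053), TLR9 (-0.003), ADAM9 (0.033) and ATP5PB (0.006). In TEA_2 against TEA_3 they were CD79B (-0.043), NLRC4 (0.008) and CX3CL1 (-0.055). In TEA_1 against TEA_3, genes that had been lower were HPGDS (0.082), CCL18 (0.553), AIM2 (0.058), CASP5 (0.096), NLRC4 (0.306), NAIP (0.521), TLR8 (0.334), FCGR3A (0.030), FCER1G (0.112) and FN1 (0.414). Further ones were ADAM9 (0.508), CD163 (0.449), NPC1 (0.157), ATP6V1H (0.020), MT2A (0.319) and HSPH1 (0.023). Genes that had been higher there were GZMH (-0.103), CD79B (-0.031), MZB1 (-0.010), ALAS2 (-0.013), GP1BA (-0.038), TREML1 (-0.042), IL17A (-0.012), HLA-DOB (-0.022), OR2L3 (-0.059) and OR2H2 (-0.004). With the 5 cell marker scores as covariates, P2RY14 (-0.006) and CIMAP3 (-0.045) turned in TEA_1 against CONTROL. In TEA_1 against TEA_3, the same covariates turned CD24 (-0.072), CCL18 (0.264), IER3 (-0.016), CXCL1 (-0.045), IRAK2 (-0.121), FN1 (0.442), VSIG4 (0.126), CD163 (0.049), PFKFB3 (-0.065) and MT2A (0.002). The cause was not tested.

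Among list scores, 15 of 1673 values turned direction, 106 lost the threshold, 51 gained it and 1501 kept both, and 0 turned after centring or quantile normalization. By the median over the list, mast cell and basophil markers (0.237), chemokine ligands (0.165) and small nucleolar RNAs (0.098) turned in TEA_1 against TEA_3. With brighter members alone, small nucleolar RNAs turned in TEA_1 against TEA_3 (0.138). The cell cycle score turned with brighter members in TEA_1 against CONTROL (0.171), TEA_3 against CONTROL (-0.134), TEA_1 against TEA_2 (0.187), TEA_1 against TEA_3 (0.305) and TEA_2 against TEA_3 (0.119). All 9 of these list values passed the threshold in the new direction. With the olfactory receptor score removed, platelet markers turned in TEA_1 against TEA_2 (-0.014) and TEA_1 against TEA_3 (-0.004). Markers of B and plasma cells (-0.035), eicosanoid genes (0.070) and lysosome genes (0.009) turned in TEA_1 against TEA_3, and lysosome genes in TEA_2 against TEA_3 (0.026). The cause was not tested. Of 280 camera tests, 65 lost the threshold with an estimated correlation.

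Overlaps of calls fell at an adjusted p under 0.01, to 2 lower in TEA_1 and TEA_2, 8 higher and 9 lower in TEA_1 and TEA_3, and 1 lower in TEA_2 and TEA_3. With genes above the median level only, they were 0, 36 and 0 lower for these pairs. With separate CONTROL arrays for each contrast, which leaves fewer samples, the mean overlap was 0.2 higher and 1.7 lower in TEA_1 and TEA_2, 1.75 and 4.25 in TEA_1 and TEA_3, and 0.6 lower in TEA_2 and TEA_3. With genes scaled to unit variance, the share between groups was 6.94% for the second component (permutation p = 0.0458) and 7.34% for the fourth (p = 0.0406). It was 0.66% for the fifth (p = 0.866). These p-values were not adjusted over the 5 components, so a pass of the threshold was not shown. Components were paired with those of unscaled genes by rank alone, so they can be different axes. The cause was not tested.

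Single arrays of the 3 smaller groups were left out in turn, 65 in all. In asthma against CONTROL the counts ran from 1 to 16 higher and from 8 to 30 lower. In TEA_1 against CONTROL they ran from 3694 to 6742 and from 1406 to 2470, with both lowest counts without CONTROL 3. In TEA_2 against CONTROL they ran from 0 to 2 and from 2 to 10, the highest count of lower genes without CONTROL 1. In TEA_3 against CONTROL they ran from 129 without CONTROL 6 to 1351 without CONTROL 3, and from 508 without CONTROL 10 to 4492 without CONTROL 3. Between clusters no array moved a count by over 1.5 times: 5944 to 6654 and 1203 to 1505 in TEA_1 against TEA_2, 9946 to 10037 and 4861 to 4950 in TEA_1 against TEA_3, and 4653 to 5194 and 1952 to 2257 in TEA_2 against TEA_3.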

Other observations

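The relations of this part were chosen only after the group differences were seen. Within groups, 8 relations of the olfactory receptor score with gene lists were computed, each with a permutation p. With oxidative phosphorylation genes, Pearson's r was -0.37 in TEA_1 (n = 34; p = 0.0337, adjusted p = 0.0449; Spearman's rho -0.29, adjusted p = 0.25), -0.01 in TEA_2 (n = 19; p = 0.981, adjusted p = 0.981; rho -0.02, adjusted p = 0.926), -0.38 in TEA_3 (n = 47; p = 0.0092, adjusted p = 0.0245; rho -0.21, adjusted p = 0.265) and -0.81 in CONTROL (n = 12; p = 0.00134, adjusted p = 0.00536; rho -0.66, adjusted p = 0.0938). Without the 2 arrays farthest from the median score, r was -0.44, 0.13, -0.21 and -0.91. Differences in r between groups were not tested.

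With lysosome genes, Pearson's r was -0.54 in TEA_1 (p = 8.6e-04, adjusted p = 0.00536; rho -0.44, adjusted p = 0.0758), -0.20 in TEA_2 (p = 0.409, adjusted p = 0.468; rho -0.15, adjusted p = 0.605), -0.33 in TEA_3 (p = 0.0223, adjusted p = 0.0447; rho -0.16, adjusted p = 0.37) and -0.60 in CONTROL (p = 0.0325, adjusted p = 0.0449; rho -0.45, adjusted p = 0.265). Without the 2 farthest arrays it was -0.44, 0.07, -0.13 and -0.69. By Spearman's rho 0 of the 8 relations passed the adjustment.

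Small nucleolar RNAs had score differences of 0.033 (adjusted p = 0.529) in asthma against CONTROL, 0.014 (0.822) in TEA_1 against CONTROL, 0.003 (0.937) in TEA_2 against CONTROL and 0.059 (0.222) in TEA_3 against CONTROL. Between clusters their score differed by -0.046 (adjusted p = 0.195) in TEA_1 against TEA_3, where 72 of 175 were higher and 17 lower and the median difference was 0.08, opposite in sign to the score.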
